A study of Mus musculus with 12 samples.

How the data were processed

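Expression was measured in F9 cells, a mouse teratocarcinoma line, on 12 Affymetrix mouse expression arrays. Per the labels' protocols, WT cells and cells labelled RARaKO (a knockout of the retinoic acid receptor alpha gene, Rara) were plated 16 h before treatment. They were pretreated for 30 min with the protein synthesis inhibitor cycloheximide at 1 µg/ml. They then received all-trans retinoic acid (atRA) at 1 µM or the ethanol vehicle at 0.1% for 7.5 h, for a total of 8 h in cycloheximide. Biotinylated cRNA was prepared from 5 µg of total RNA, per the labels' protocols. The 4 groups (WT vehicle, WT atRA, RARaKO vehicle, RARaKO atRA) held 3 arrays each, numbered by set as 2, 3 and 4, and these set numbers are used here as replicate numbers. All 12 arrays were used, and their number limits the precision of every value.

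The deposited values are expression values per probe set, taken here as log2, the scale that GCRMA gives. Per the submitters' processing notes the arrays were processed with GCRMA, whose version is not given there. Testing the deposited values showed that each probe set had been centred on its own median over the 12 arrays, a step that no label records, so absolute expression levels are not in these values. No label states the log base. The values moved in steps of 2 to the power of -20, -21 or -22, the single-precision spacing of numbers from 8 to 16, 4 to 8 and 2 to 4, and a log10 scale cannot reach such numbers, while a natural logarithm is not excluded by them. These steps gave a coarse class of the lost level: 38.5% of probe sets had a median of at least 8, 61.3% between 4 and 8, and 0.284% under 4. Among 111 probe sets of ribosomal protein genes 93 fell in the highest class, against 4 of 27 for olfactory receptor genes. In a simulation of 20000 probe sets the class was right for 98.7%.

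Of 37661 probe sets, 61 controls were left out and 37600 were tested. A symbol came from the probe annotation: 30488 probe sets carried a single symbol, for 16509 genes, 784 carried several, and 6328 had none. Probe sets with several symbols or none were tested but not named. The planned filters (a log2 level of at least 4, or of at least 6, in at least 3 arrays) and the planned intensity trend in the variance need levels, so neither could be applied as planned. By the recovered class only 0.284% of probe sets had a median under 4, so the filter at 4 would have left out few of them. All 37600 probe sets were therefore used throughout, and a minimum class of 8 and a variance prior per class were chosen as replacements after the data had been seen. Where a gene had several probe sets, a single probe set stood for it: the highest recovered class, then the least ambiguous probe set type, then the lowest identifier number. This replaced the planned choice by highest mean.

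Differences were computed with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 4.60 prior degrees of freedom). All 12 arrays entered 1 fit with a mean per group and no block. P-values were two-sided and adjusted by Benjamini-Hochberg over the 37600 probe sets, and an adjusted p under 0.05 was called. Such p-values measure the spread between these arrays, which may be technical, since the labels describe the replicates only as sets. Errors after ± are the standard errors of the fit, with 3 arrays per group. The 5 comparisons were the response to atRA in each genotype, the difference between these responses, and RARaKO against WT in vehicle and in atRA. The responses shared no arrays with each other, nor did the genotype comparisons. Their overlaps were set against the product of the list sizes divided by the number of probe sets. All comparisons drew on the same variance per probe set, so their lists are not independent, and this product is a reference value only.

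The design, 21 gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The rule took, per comparison, the 10 largest increases and 10 largest decreases among called genes whose 3 arrays of a group all lay above or below the 3 of the other. It added up to 4 members of each list with the smallest p, and genes to be named throughout, of which Rara, Rarb, Rarg and Cyp26a1 are used here. Other list members are named without values where they complete a count of called members. The imprinted and cholesterol synthesis lists were fixed knowing that the study's published interest lay there, so they are not free of that knowledge. Lists were tested with camera of limma on the probe set chosen for each gene, with a preset correlation of 0.01 and adjustment over the 21 lists of a comparison. Camera with an estimated correlation (statmod 1.5.0) was run beside it. So was fry for a shift of the list in 1 direction, which is given where it did not call a list that camera called. The form of fry for change in either direction called 65 of the 105 lists over the 5 comparisons and is not used. The lists covered known retinoic acid targets, Hox genes, retinoid uptake and metabolism, nuclear receptors, pluripotency, extraembryonic endoderm, neural, mesoderm, fibroblast and trophoblast markers, imprinted genes, chromatin, germline genes, cholesterol synthesis, immediate-early genes, stress, cell cycle, FGF and ERK feedback, Wnt targets, BMP and TGF-beta targets, and housekeeping genes.

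The set numbers are shared between groups, so same-numbered arrays were checked for pairing. After removal of group means, 15 of the 18 same-numbered pairs correlated above 0.1 across probe sets (median 0.192, smallest 0.0186), against a median of -0.110 for other pairs between groups. Removing group means makes the residuals within a group cancel, so the negative median largely follows from the positive one and is not a separate contrast. Each of the 12 arrays correlated best with the arrays of its own number. Within comparisons the smallest of the 3 pairs was 0.101 for the WT response, 0.117 for the RARaKO response, 0.116 for the genotypes in vehicle and 0.0375 for the genotypes in atRA. The first 3 therefore met the rule for pairing and their counts are given with the set as a block too.

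Neighbouring genes were examined after the data had been seen, with the gene order of the GRCm38.p6 annotation, which is not stated to be the build behind the arrays and so gives no coordinates here. The segment was the run of consecutive genes with the largest sum of log2 differences less an offset of 0.2 in the vehicle arrays. Its median was bootstrapped over genes with 2000 resamples and set against 10000 random gene sets of the same size. Alternatives to the fit were array weights, a fit limited to the groups compared, quantile normalization of the centred values, and centring of each array. Others were the set as a fixed or random block, 1 probe set per gene, and an added minimum of 1 log2 unit. Each set and each array was also left out. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

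The fit was tested on simulated data, with 200 of the 37600 probe sets changed by known sizes. At log2 changes of 0.5, 1 and 2 the share called was 64.2%, 98.5% and 100% for the WT response and 65.7%, 97.0% and 100% for the RARaKO response. For the difference between responses the shares were 38.8%, 88.1% and 100%. The genotype comparisons gave 55.2%, 92.5% and 100% in vehicle and 67.2%, 94.0% and 100% in atRA. Between 4 and 7 unchanged probe sets were called per comparison. The shares called hold with 200 probe sets changed and with noise drawn independently for each array. With fewer changed probe sets the adjustment is stricter, so the shares do not tell which differences an absence of calls excludes. With every other member of a list of 26 genes shifted by 0.3 in the WT response, camera called it in 20 of 20 simulations. It called 1 of 400 unchanged lists. That noise was also drawn independently for each gene, while the estimated correlation within the real lists was up to 0.320 (pluripotency). The simulation therefore does not tell how often camera calls an unchanged list of correlated genes.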

Results

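The data were 12 arrays of F9 teratocarcinoma cells, 3 per group: WT and RARaKO cells, each given vehicle or 1 µM atRA in cycloheximide. F9 cells resemble early embryonic cells and differentiate when given retinoic acid, the ligand of the nuclear receptors encoded by Rara, Rarb and Rarg. Probe set identifiers stand in the plots per array. Values are expression on a scale taken as log2, relative to each probe set's median over the 12 arrays, so differences between groups are meaningful while levels are not in the data. In a principal component analysis the first component took 32.9% of the variance and placed the 6 RARaKO arrays between -28.3 and -9.10 and the 6 WT arrays between 11.2 and 19.5.

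The targeted gene, Rara, was read by a single probe set, and its values lay higher, not lower, in the arrays labelled RARaKO. In vehicle the mean was 0.30 ± 0.02 (SD, n = 3) in RARaKO and -0.60 ± 0.14 (SD, n = 3) in WT, a log2 difference of 0.90 ± 0.09 (limma, adjusted p = 1.50e-04). In atRA the difference was 0.36 ± 0.09 (adjusted p = 0.0488). The labels do not say how the gene was knocked out or whether part of it was removed. This probe set may go against the label, or it may read a part of the gene that is still transcribed. These cannot be told apart here, so the probe set does not settle the genotype label. The arrays are therefore called arrays labelled RARaKO, and every direction drawn from the genotype rests on that label. Rarb, itself a retinoic acid target, was higher in the arrays labelled RARaKO in vehicle by 0.54 ± 0.09 (adjusted p = 0.00394), and in atRA its difference was 0.14 ± 0.09 (adjusted p = 0.424). Rarg was called in none of the 5 comparisons, with -0.06 ± 0.07 between genotypes in vehicle (adjusted p = 0.784).

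The response of WT cells asks which transcripts changed with atRA while protein synthesis was inhibited. Cdx1, a homeobox gene of the posterior embryo, rose 3.33-fold (log2 1.74 ± 0.13, adjusted p = 5.18e-05), and Hoxb5 rose 3.10-fold (1.63 ± 0.13, adjusted p = 5.93e-05). Rarb and Cyp26a1, which encodes the enzyme that breaks down retinoic acid, each rose 2.55-fold (1.35 ± 0.09 and 1.35 ± 0.08). Csn3 (kappa-casein, 1.57 ± 0.10), Pdgfrb (a growth factor receptor, 1.46 ± 0.17), Aurkc (a meiotic kinase, 1.32 ± 0.09), Hoxa5 (1.28 ± 0.22), Hoxa4 (1.25 ± 0.16) and Ncmap (1.18 ± 0.13) completed the 10 largest increases. Decreases were smaller. Cdh9, a cadherin, fell by 0.80 on the log2 scale (± 0.13), Sema3c, a secreted guidance factor, fell by 0.78 (± 0.13), AW551984 fell by 0.78 (± 0.12), and St8sia4, a polysialic acid synthase, fell by 0.73 (± 0.12). Id4, an inhibitor of helix-loop-helix factors, Pim2, a kinase, and Neurog3, an endocrine fate factor, fell by 0.63, 0.61 and 0.59. Slc27a2, Efnb2 and Sned1 fell by 0.53, 0.50 and 0.49.

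In WT cells 12 of the 26 measured known retinoic acid targets rose and none fell, while 17 rose when adjusted over the list alone. The list as a whole lay higher than other genes (camera adjusted p = 1.40e-36, and 6.07e-05 with an estimated correlation). Beside those above, Dhrs3, a retinaldehyde reductase, rose by 1.06 ± 0.09, Stra6, the retinol uptake receptor, by 0.83 ± 0.11, Stra8, a gene of meiotic entry, by 0.94 ± 0.09, and Foxa1, an endoderm transcription factor, by 0.66 ± 0.09. Among 30 Hox genes 6 rose (Hoxa2, Hoxa4, Hoxa5, Hoxb1, Hoxb2 and Hoxb5; 10 when adjusted over the list alone), and the list was called (adjusted p = 3.65e-09, and 0.00561 with an estimated correlation). Hoxb1 rose by 1.11 ± 0.11 and Hoxb2 by 0.99 ± 0.10. Of 31 nuclear receptors and co-regulators 3 rose (5 when adjusted over the list alone): Rarb, Rara (0.45 ± 0.09) and the corepressor gene Nrip1 (1.06 ± 0.18). That list was called too (adjusted p = 0.00366, and 0.0295 with an estimated correlation), but not without set 2 (0.0990). Of 28 primitive streak and mesoderm genes 2 rose, Cdx1 and Snai1 (0.51 ± 0.07), both also when adjusted over the list alone. The call (adjusted p = 0.0185) was lost with an estimated correlation (adjusted p = 0.116), without set 2 (0.119), without set 3 (0.0531) and with the mean of all probe sets of a gene (0.0685).

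Single members moved in lists that were not called as a whole in WT. Cyp26a1, Stra6 and Dhrs3 were the 3 of 28 genes of retinoid uptake and metabolism that rose (camera adjusted p = 0.861). Fgfr4 (0.64 ± 0.07) and Dusp5 (0.60 ± 0.06), a phosphatase that acts on ERK, rose among 23 FGF and ERK genes. Stra8 and Kit (0.75 ± 0.09) rose among 36 germline genes, and Eras (0.48 ± 0.08) rose while Myc (-0.36 ± 0.07) fell among 39 pluripotency genes. Sox3 (0.86 ± 0.12), Pdgfrb, Cdc25b (0.52 ± 0.08), Smad6 (0.55 ± 0.08) and Peg12 (0.42 ± 0.07) were each the sole member that rose in the neural, fibroblast, cell cycle, BMP and TGF-beta, and imprinted lists. No member of the trophoblast, chromatin, cholesterol synthesis, stress and p53, or housekeeping lists passed the test (limma), and Foxa1 was the sole extraembryonic endoderm gene that did.

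In all, 214 of 37600 probe sets were called in WT, 182 higher and 32 lower, and 30 of them, all higher, changed by at least 1 log2 unit. They named 137 genes that rose and 26 that fell. The mean 5' minus 3' difference of Actb, Gapdh, Tfrc and Pcx, read from control probe sets, also parted these groups: it was -0.0899, -0.123 and -0.0844 in vehicle and 0.0179, -0.0248 and -0.0128 in atRA. Taken singly, Tfrc alone parted them, and barely (highest -0.114 in vehicle, lowest -0.112 in atRA), while Actb, Gapdh and Pcx overlapped. With the set as a block the count was 339, with array weights it was 382, and without any single one of its 6 arrays it lay between 107 (WT atRA replicate 4) and 128 (WT atRA replicate 2). Of 38 named calls 25 held without each single array; those lost were Hoxa5, Nrip1, Rara, Eras, Peg12, Myc, Cdh9, Sema3c, St8sia4, Pim2, Neurog3, Slc27a2 and Efnb2, and the call of Rara was also lost with the set as a block.

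**Figure D1:**
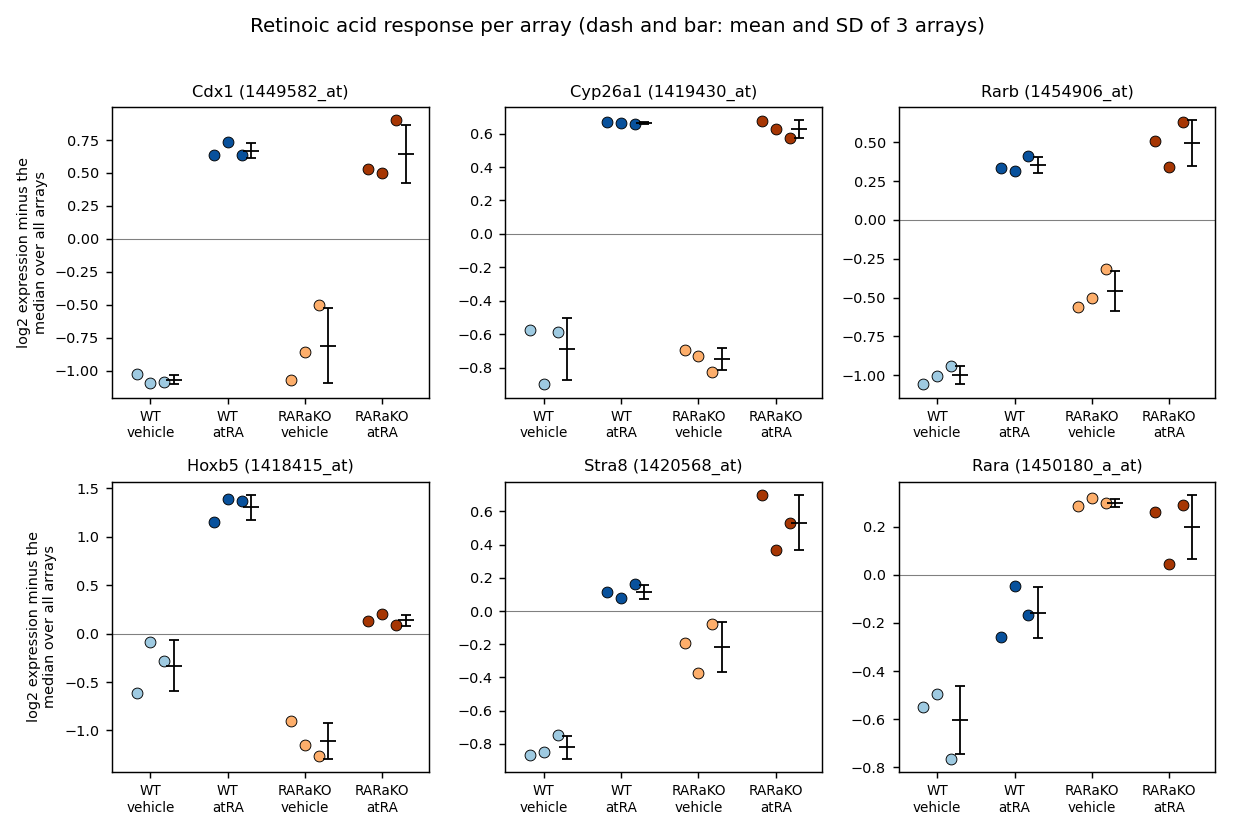
Each panel plots 1 probe set: the y axis is log2 expression minus the probe set's median over the 12 arrays, each point is an array, and the dash and bar are the mean and SD of the 3 arrays of a group. Cdx1, Cyp26a1, Rarb, Hoxb5 and Stra8 lay higher with atRA in both genotypes, while Rara lay higher in the arrays labelled RARaKO and rose in WT (0.45).

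The response in the arrays labelled RARaKO asks which transcripts still changed with atRA. Cdx1 rose 2.74-fold (log2 1.45 ± 0.13, adjusted p = 4.05e-04), Cyp26a1 2.60-fold (1.38 ± 0.08, adjusted p = 2.37e-05), and Hoxb5 2.37-fold (1.25 ± 0.13). Csn3 (1.21 ± 0.10), Pdgfrb (1.13 ± 0.17), Aurkc (1.10 ± 0.09), Ncmap (1.09 ± 0.13), 1700031F05Rik (1.06 ± 0.19), Nrip1 (1.00 ± 0.18) and Tmtc1 (0.98 ± 0.13) completed the 10 largest increases, and Rarb rose 1.94-fold (0.95 ± 0.09). Cdh9 fell by 0.71 (± 0.13), Dapp1 by 0.59 (± 0.11), Nr5a1, a nuclear receptor of steroid-producing tissue, by 0.54 (± 0.08), and Myc by 0.48 (± 0.07). Kctd12b, Id4 and Foxd3, a pluripotency factor, fell by 0.48, 0.45 and 0.44, and Aoah, Clvs2 and Tyro3 fell by 0.41, 0.40 and 0.37. Rara differed by -0.10 ± 0.09 (adjusted p = 0.839).

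Of the 26 known retinoic acid targets 10 rose in the arrays labelled RARaKO and none fell, with 17 when adjusted over the list alone (camera adjusted p = 2.18e-30, and 1.24e-04 with an estimated correlation). Among them Stra6 rose by 0.81 ± 0.11, Stra8 by 0.75 ± 0.09 and Dhrs3 by 0.71 ± 0.09. Of 30 Hox genes 4 rose, Hoxa4 (0.91 ± 0.16), Hoxb1 (0.74 ± 0.11), Hoxb2 (0.68 ± 0.10) and Hoxb5, with 9 when adjusted over the list alone (adjusted p = 4.62e-07, and 0.0134 with an estimated correlation). Rarb and Nrip1 rose among 31 nuclear receptors and co-regulators, the same count as when adjusted over the list alone. That call (adjusted p = 0.0253) was lost with an estimated correlation (adjusted p = 0.0741), without RARaKO atRA replicate 2 (0.102) and without sets 2 and 3 (0.0535 and 0.104). The pluripotency list lay lower (adjusted p = 0.0321), with 2 of 39 members fallen, Foxd3 and Myc, also when adjusted over the list alone. Its adjusted p was 0.780 with an estimated correlation, 0.541 with fry, and 0.0893 without the genes of the chromosome 4 segment described further on, which holds Foxd3. It was 0.0535 without set 2 and 0.136 without set 3.

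In lists not called as a whole, Cyp26a1, Stra6 and Dhrs3 rose among the genes of retinoid uptake and metabolism, Fgfr4 (0.57 ± 0.07) and Dusp5 (0.37 ± 0.06) among FGF and ERK genes, Stra8 and Kit (0.53 ± 0.09) among germline genes, and Snai1 (0.50 ± 0.07) and Cdx1 among mesoderm genes. Cdc25b rose by 0.46 ± 0.08, and Gap43, a growth cone protein gene, fell by 0.36 (± 0.06). No member of the extraembryonic endoderm, trophoblast, imprinted, chromatin, cholesterol synthesis, stress and p53, or housekeeping lists passed the test (limma). In all, 99 probe sets were called, 81 higher and 18 lower, with 13 higher by at least 1 log2 unit, for 67 genes that rose and 17 that fell. The count was 167 with the set as a block, 14 when the fit held these 6 arrays alone, 57, 39 and 55 without RARaKO vehicle replicates 2, 3 and 4, and 56 and 61 without RARaKO atRA replicates 3 and 4. Of 33 named calls 12 held without each single array: Cdx1, Cyp26a1, Hoxb5, Csn3, Aurkc, Ncmap, Tmtc1, Rarb, Stra8, Stra6, Dhrs3 and Fgfr4. When the fit held these 6 arrays alone 6 of the 33 held, and without a whole set 1 to 7 did.

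Whether the genotype altered the response to atRA was tested as the difference between the 2 responses. No probe set was called (limma, smallest adjusted p = 1.00), and 1168 had an unadjusted p under 0.05 where 1880 of 37600 would by chance. Cyp26a1 differed by 0.03 ± 0.12, Rarb by -0.40 ± 0.12, Rara by -0.55 ± 0.12, Hoxb5 by -0.39 ± 0.18, Hoxb1 by -0.37 ± 0.16 and Tgm2, a transglutaminase gene, by -0.50 ± 0.14. In size, the median standard error of this difference was 0.124, against 0.0878 for a single response. As a list, the 26 known retinoic acid targets lay lower in the difference (mean -0.10, median -0.03, camera adjusted p = 0.0191), with 0 members called in either direction, also when adjusted over the list alone. That call was lost with an estimated correlation (adjusted p = 0.377), with fry (0.998) and without set 2, 3 or 4 (adjusted p = 0.0586, 0.266 and 0.0709). None of the other 20 lists was called, and the next smallest adjusted p, shared by the Hox and cholesterol synthesis lists, was 0.320.

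The 2 responses overlapped widely, though both drew on the variance of the same fit, so the lists are not independent. Of the probe sets called higher, 77 were shared where 0.392 would be for independent lists, and of those called lower 8 were shared where 0.0153 would be. None was called in opposite directions. Of the 214 probe sets called in WT, 213 moved the same way in the arrays labelled RARaKO, with a median of 0.43 against 0.55 in WT, where they had been chosen. All 99 called in the arrays labelled RARaKO moved the same way in WT, with a median of 0.64 in WT against 0.58. Of these 99, 70 changed more in WT than in the arrays labelled RARaKO, where they had been chosen (65 to 72 with 1 array left out). That count was not tested. Across the 37600 probe sets, which are not independent replicates, the responses had Pearson's r = 0.468 and Spearman's rho = 0.322. The shared count (85 in all) fell to 62 without RARaKO atRA replicate 2 and lay between 2 and 17 without a whole set.

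**Figure D2:**
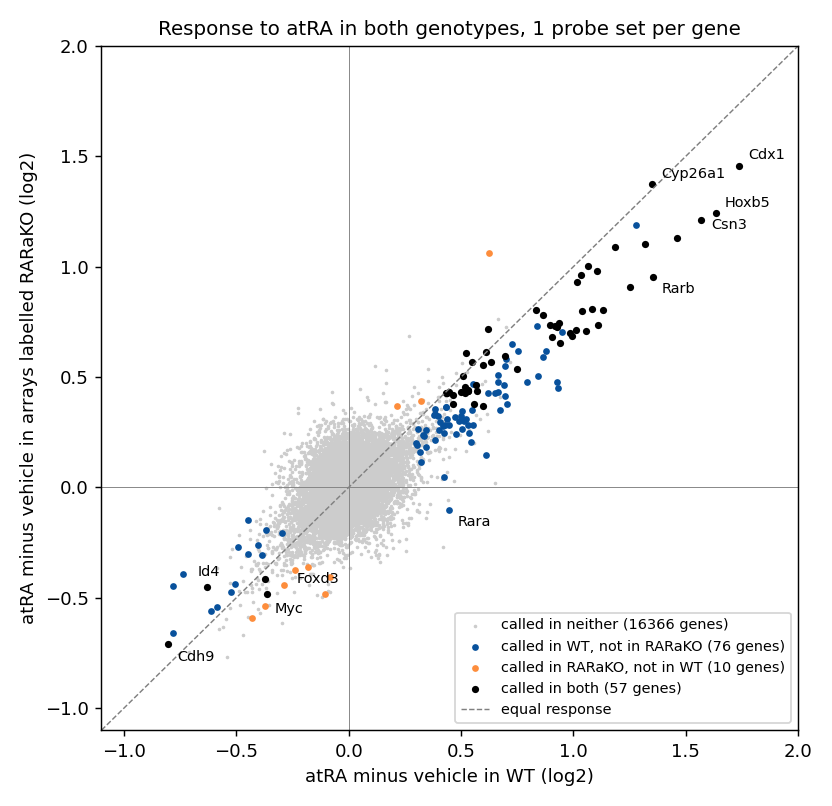
Each point is a gene (16509, 1 probe set each), with its atRA minus vehicle difference in WT on the x axis and in the arrays labelled RARaKO on the y axis, both in log2; colours mark where limma called it. The 57 genes called in both moved the same way in both genotypes, with Cdx1 at 1.74 and 1.45, below the dashed line of equal response, and Cyp26a1 at 1.35 and 1.38, on it.

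The genotypes in vehicle show what differed without atRA. Slc38a4, an imprinted amino acid transporter gene, was 7.92-fold higher in the arrays labelled RARaKO (log2 2.99 ± 0.16, adjusted p = 1.10e-06). Rpl39l, a ribosomal protein gene of the germline, was 5.08-fold higher (2.34 ± 0.11), and Stmn2, a neuronal microtubule regulator, 4.45-fold higher (2.15 ± 0.23). Mobp (1.40 ± 0.18), 2410003I16Rik (1.21 ± 0.20), Dnajc6 (1.21 ± 0.09), Tusc1 (1.17 ± 0.10), Sema3e (1.14 ± 0.13), Cstf2t (1.07 ± 0.08) and Rex2 (1.05 ± 0.15) followed; Dnajc6 and Tusc1 belong to the chromosome 4 segment. Gab1, a docking protein downstream of receptor tyrosine kinases, was 4.89-fold lower (-2.29 ± 0.07, adjusted p = 3.24e-09). Mest, an imprinted gene, was 4.42-fold lower (-2.14 ± 0.11), and Tex13b 2.61-fold lower (-1.39 ± 0.08). Nkx6-3 (-1.27 ± 0.20), Tbx15 (-0.93 ± 0.14), Ttyh3 (-0.92 ± 0.12), Cux1 (-0.90 ± 0.08), Mmp11 (-0.87 ± 0.08), Spire1 (-0.87 ± 0.13) and Ildr1 (-0.83 ± 0.09) were lower too, though 1 of the 9 probe sets of Cux1 was called higher.

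Of 36 germline genes 9 were higher in the arrays labelled RARaKO in vehicle and none lower (9 and 2 when adjusted over the list alone). They were Rhox6 (0.98 ± 0.07), Syce1 (0.62 ± 0.09), Stra8 (0.61 ± 0.09), Stk31 (0.58 ± 0.09), Tex19.1, Dazl, Rhox9, Rhox13 and Kit (camera adjusted p = 7.19e-05, and 0.326 with an estimated correlation). Of 54 imprinted genes 4 were higher, Slc38a4, Sfmbt2 (1.02 ± 0.17), Mkrn3 and Peg12, and 3 lower, Mest, Grb10 (-0.50 ± 0.08) and Inpp5f, with 5 and 4 when adjusted over the list alone. As a list they were not called in either direction (camera adjusted p = 0.760). Hox genes lay lower, with Hoxb5 (-0.78 ± 0.13) and Hoxb1 (-0.65 ± 0.11) called of 30 and 4 when adjusted over the list alone (adjusted p = 0.00149, and 0.235 with an estimated correlation). Of 40 cell cycle genes 2 were lower, the inhibitor gene Cdkn1a (-0.43 ± 0.06) and Rb1 (-0.47 ± 0.10), which both restrain the cycle, and 1 was higher, Cdc20 (0.39 ± 0.06), in the segment. The counts were 3 and 1 when adjusted over the list alone, and the list lay lower (adjusted p = 5.84e-04, and 0.426 with an estimated correlation).

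The stress and p53 list and the FGF and ERK list lay lower in vehicle too. Perp (-0.34 ± 0.08) and Cdkn1a were the called members of 29 stress and p53 genes, 8 when adjusted over the list alone (adjusted p = 0.0144, and 0.642 with an estimated correlation). That call was lost with fry (0.0896), with the mean of all probe sets of a gene (0.181) and without set 3 (0.0743). Gab1, Egr1 (-0.58 ± 0.14) and Fgfr4 (-0.40 ± 0.07) were lower and Dusp5 (0.42 ± 0.06) higher among 23 FGF and ERK genes, with 5 and 1 when adjusted over the list alone (adjusted p = 0.0243, and 0.623 with an estimated correlation), a call lost with the mean of all probe sets of a gene (0.260) and without set 4 (0.146). Of the known retinoic acid targets 3 were higher, Rarb, Stra8 and Foxa1 (0.48 ± 0.09), and 3 lower, Hoxb1, Meis1 and Meis2 (camera adjusted p = 0.350). The neural list was not called, with Stmn2, Tubb3 (0.65 ± 0.14) and Elavl4 (0.48 ± 0.10, in the segment) higher and Dcx and Gap43 lower. Hmgcs1, the synthase of the sterol pathway, was the sole cholesterol synthesis gene called of 20 (-0.79 ± 0.12). Among pluripotency genes Rex2 and L1td1 (0.38 ± 0.06, in the segment) were higher and Myc (-0.35 ± 0.07) lower, and among immediate-early genes Jun (0.51 ± 0.07, in the segment) was higher and Egr1 and Myc lower. Rara and Rarb of the nuclear receptors, Rdh11 and Dhrs4 of retinoid metabolism, Amn, Foxa1 and Hhex of the endoderm list and Suv39h2 of the chromatin list were the called members there. No member of the mesoderm, fibroblast, trophoblast, Wnt, BMP and TGF-beta, or housekeeping lists passed the test (limma).

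In all, 1131 probe sets were called between genotypes in vehicle, 693 higher and 438 lower, with 36 higher and 8 lower by at least 1 log2 unit, for 490 genes higher and 326 lower. The mean 5' minus 3' difference of the 4 control genes again parted the groups compared: it was 0.0733, -0.0227 and 0.132 on the RARaKO vehicle arrays, against -0.0899, -0.123 and -0.0844 on the WT vehicle arrays. Taken singly, Tfrc alone parted them here too (lowest -0.0684 in RARaKO, highest -0.114 in WT), while Actb, Gapdh and Pcx overlapped. The count was 1972 with the set as a block, 2071 with array weights, 619 and 545 without RARaKO vehicle replicates 2 and 3, and 694 and 587 without WT vehicle replicates 3 and 4. The balance of directions moved too: it was 594 higher and 190 lower without WT vehicle replicate 2, 560 and 93 without set 2, and 581 and 554 at a level class of at least 8. Of 50 named calls 38 held without each single array, and those lost were Foxa1, Rdh11, Myc, Hhex, Amn, Gap43, Tubb3, Elavl4, Suv39h2, Egr1, Perp and Rb1.

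**Figure D3:**
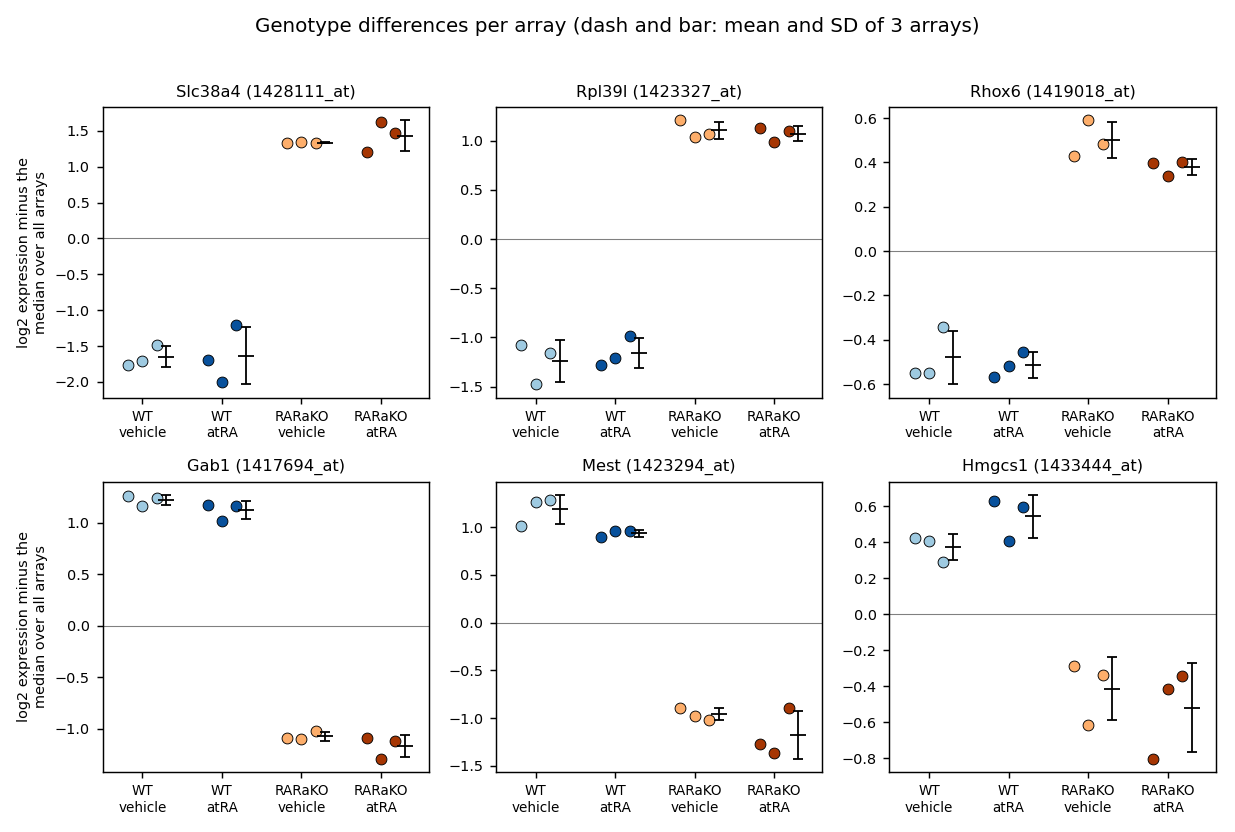
Each panel plots 1 probe set: the y axis is log2 expression minus the probe set's median over the 12 arrays, each point is an array, and the dash and bar are the mean and SD of the 3 arrays of a group. In both treatments Slc38a4, Rpl39l and Rhox6 lay higher and Gab1, Mest and Hmgcs1 lower in the 6 arrays labelled RARaKO than in the 6 WT arrays.

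With atRA present Slc38a4 was 8.40-fold higher in the arrays labelled RARaKO (3.07 ± 0.16, adjusted p = 6.76e-07), Rpl39l 4.69-fold (2.23 ± 0.11) and Stmn2 4.04-fold (2.01 ± 0.23), followed by Mobp (1.39 ± 0.18), Dnajc6 (1.31 ± 0.09, in the segment), Gm17546 (1.19 ± 0.16), Sema3e (1.18 ± 0.13), Sfmbt2 (1.15 ± 0.17), Tusc1 (1.10 ± 0.10, in the segment) and Gm13261 (1.02 ± 0.10). Gab1 was 4.86-fold lower (-2.28 ± 0.07, adjusted p = 2.76e-09), Mest 4.32-fold (-2.11 ± 0.11), Tex13b 2.91-fold (-1.54 ± 0.08) and Nkx6-3 2.55-fold (-1.35 ± 0.20). Hoxb5 (-1.17 ± 0.13), Hmgcs1 (-1.06 ± 0.12) and Hoxb1 (-1.02 ± 0.11) were among the 10 largest decreases here, with Ildr1 (-1.02 ± 0.09), Cux1 (-1.01 ± 0.08, with 1 of 9 probe sets again called higher) and Ttyh3 (-0.97 ± 0.12).

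Of 30 Hox genes 5 were lower in the arrays labelled RARaKO with atRA and none higher: Hoxb5, Hoxb1, Hoxb13 (-0.84 ± 0.15), Hoxb2 (-0.63 ± 0.10) and Hoxc10, with 8 when adjusted over the list alone (camera adjusted p = 2.11e-04, and 0.0939 with an estimated correlation). Of 36 germline genes 6 were higher, Rhox6 (0.89 ± 0.07), Rhox9 (0.85 ± 0.13), Syce1 (0.61 ± 0.09), Tex19.1 (0.58 ± 0.11), Stra8 and Sycp1, and Piwil2 was lower, with 9 and 1 when adjusted over the list alone (adjusted p = 9.36e-04, and 0.460 with an estimated correlation). The cell cycle list lay lower, with Cdkn1a (-0.50 ± 0.06), Rb1 (-0.54 ± 0.10), Cdc25b (-0.35 ± 0.08) and Ccne2 called lower and Cdc20 (0.46 ± 0.06, in the segment) higher of 40, and 9 and 2 when adjusted over the list alone (adjusted p = 8.57e-04, and 0.460 with an estimated correlation). Perp (-0.45 ± 0.08), Bbc3 (-0.35 ± 0.08) and Cdkn1a were lower among 29 stress and p53 genes, 4 when adjusted over the list alone (adjusted p = 0.0144, 0.740 with an estimated correlation, 0.0891 with fry and 0.148 without set 4). Gab1, Etv4 (-0.52 ± 0.10), Fgfr4 (-0.47 ± 0.07), Fosl1 (-0.40 ± 0.07) and Fgfr1 were lower among 23 FGF and ERK genes, with 5 lower and 1 higher when adjusted over the list alone (adjusted p = 0.0396, and 0.740 with an estimated correlation). That call was lost with the mean of all probe sets of a gene (0.248), without set 2 (0.104) and without set 4 (0.172). The cholesterol synthesis list also lay lower, with Hmgcs1 called of 20 and 6 lower and 1 higher when adjusted over the list alone (adjusted p = 0.0403, and 0.759 with an estimated correlation). Cholesterol synthesis was not called with fry (adjusted p = 0.214), with the set as a block (0.120), without set 2 (0.242) or without set 3 (0.310).

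Among lists not called as a whole with atRA, the imprinted genes again went both ways, with Slc38a4 and Sfmbt2 higher and Mest, Grb10 (-0.51 ± 0.08) and Cd81 lower (camera adjusted p = 0.984). Stra8 (0.42 ± 0.09) was higher and Hoxb1, Hoxb2 and Meis2 (-0.69 ± 0.16) lower among known retinoic acid targets (camera adjusted p = 0.871). Rex2 (0.87 ± 0.15) and L1td1 (0.46 ± 0.06) were higher and Myc (-0.47 ± 0.07) and Lefty2 (-0.47 ± 0.10) lower among pluripotency genes. Stmn2, Tubb3 (0.70 ± 0.14) and Elavl4 (0.66 ± 0.10) were higher and Gap43 (-0.47 ± 0.06) and Neurod1 lower among neural genes. Rara was higher and Rxrg (-0.61 ± 0.12) and Nr6a1 (-0.41 ± 0.10) lower among nuclear receptors, Hhex (-0.66 ± 0.11) was lower among endoderm genes, and Gata3 (-0.57 ± 0.11), Mesp2 (-0.27 ± 0.06) and Tbp (-0.31 ± 0.07) were each the sole trophoblast, mesoderm and housekeeping gene called. Rdh12 was higher and Dhrs4 lower among genes of retinoid metabolism, Jun was higher and Fosl1 and Myc lower among immediate-early genes, and Lefty2 was the called member of the BMP and TGF-beta list. No member of the fibroblast, chromatin or Wnt lists passed the test (limma).

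In all, 1173 probe sets were called between genotypes in atRA, 607 higher and 566 lower, with 23 higher and 17 lower by at least 1 log2 unit, for 395 genes higher and 444 lower. The mean 5' minus 3' difference of the 4 control genes overlapped between these groups, though it was higher in RARaKO within each set. It was 0.0605, 0.0012 and 0.0897 on the RARaKO atRA arrays, against 0.0179, -0.0248 and -0.0128 on the WT atRA arrays. The count was 592 when the fit held these 6 arrays alone, and 776, 755 and 532 without RARaKO atRA replicate 2, WT atRA replicate 2 and WT atRA replicate 4. Which direction held more calls depended on the processing: 489 were higher and 842 lower at a level class of at least 8, 782 and 928 with array weights, and 345 and 406 with 1 probe set per gene, but 345 and 187 without WT atRA replicate 4. Of 55 named calls 38 held without each single array, and those lost were Rara, Stra8, Meis2, Rdh12, Rxrg, Nr6a1, Lefty2, Tubb3, Mesp2, Gata3, Tex19.1, Fosl1, Perp, Bbc3, Rb1, Cdc25b and Tbp. Between the genotype comparisons 442 probe sets were called higher in both, where 11.2 would be for independent lists, and 280 lower in both, where 6.59 would be. None was called in opposite directions. These lists also drew on the variance of the same fit and are not independent. Across probe sets, which are not independent replicates, Pearson's r was 0.742 and Spearman's rho 0.562.

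Genes called higher in the arrays labelled RARaKO lay together on chromosome 4, a feature singled out after the values had been seen. In the run of 220 measured genes from Tusc1 to Akirin1, 131 were called higher in vehicle and 131 in atRA, while 207 and 155 of the 16153 genes elsewhere were. Its bounds were chosen on the vehicle values, so all vehicle values of the run are descriptive and the test is given for atRA alone (Fisher's exact test, p = 1.90e-183; genes are not independent replicates, and the same lines were measured in both). Over the 130 genes of the run with a recovered level of at least 8, the median difference was 0.57 in vehicle (95% bootstrap interval 0.52 to 0.60) and 0.56 in atRA (0.52 to 0.60). In vehicle 97.7% of them lay above 0, and in atRA 100% did. The rest of chromosome 4 had medians of -0.02 and -0.04, and all genes outside the run had -0.02 and -0.03. The run's median was between 0.23 and 0.31 on the 6 arrays labelled RARaKO and between -0.30 and -0.25 on the 6 WT arrays. Its median response to atRA was -0.03 in WT and -0.04 in the arrays labelled RARaKO. Without these genes 786 probe sets were called in vehicle (416 higher and 370 lower) and 786 in atRA (316 and 470), and 452 were called alike in both.

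**Figure D4:**
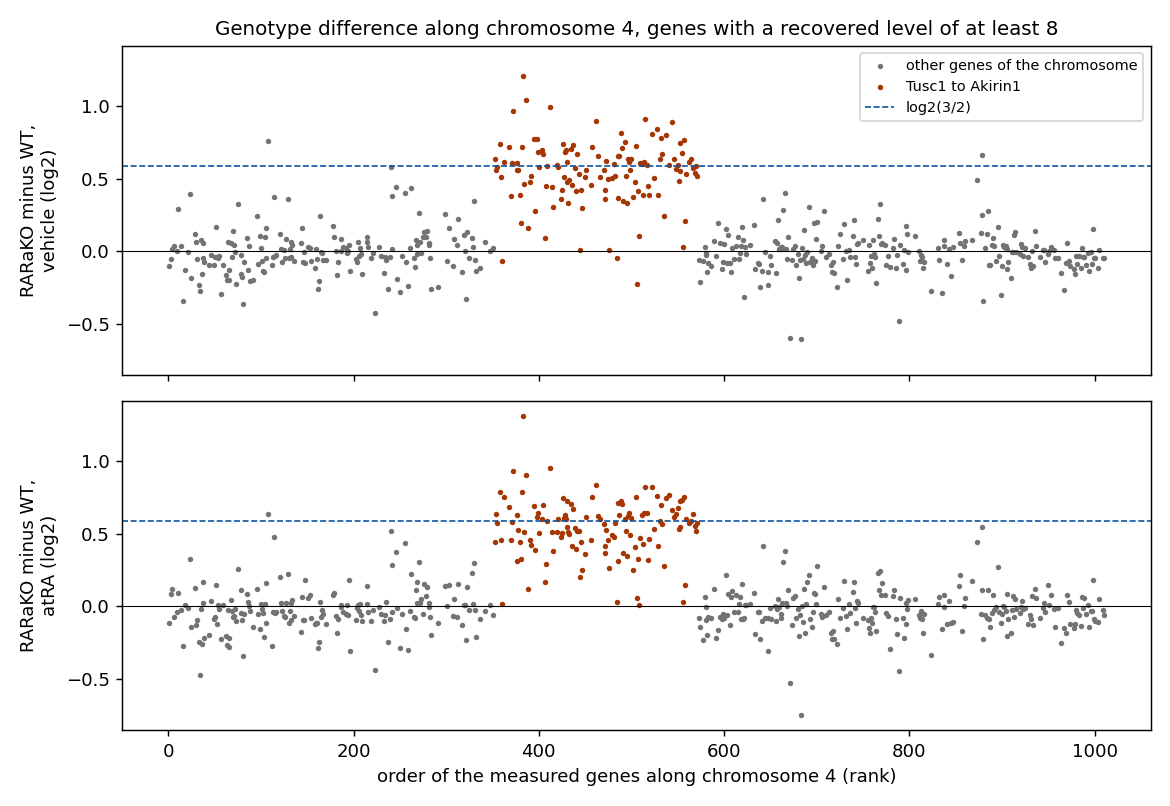
Each point is 1 of 554 genes of chromosome 4 with a recovered level of at least 8, in gene order on the x axis; the y axis is the log2 difference of the arrays labelled RARaKO from WT, in vehicle above and atRA below. Genes from Tusc1 to Akirin1 form a plateau with medians of 0.57 and 0.56, near the dashed line at the log2 of 3/2 (0.585), while the genes on both sides lie around 0.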

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

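Of the tests in this part, the random reassignment of genotypes for the gene list was chosen before its result was seen, and the others (without a single array, the differences within sets, the reassignment for single probe sets) only afterwards. The known retinoic acid targets stood out because their response to atRA was called lower in the arrays labelled RARaKO over 26 genes, by a mean log2 difference of -0.10 (camera adjusted p = 0.0191), with a median of -0.03 and 9 of 26 members above 0. The call was lost with an estimated correlation (adjusted p = 0.377), with fry (0.998) and without set 2, 3 or 4 (0.0586, 0.266 and 0.0709).

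Members with the lowest p were Rarb (-0.40 ± 0.12), Tgm2 (-0.50 ± 0.14), Dhrs3 (-0.35 ± 0.13) and Hoxa2 (-0.48 ± 0.19), none of them called (limma). A source in the array RARaKO atRA replicate 2, which stands apart from the others, is argued against, since the mean was -0.14 without it, and the Hox and pluripotency lists were then called lower as well (adjusted p = 0.0219 and 0.0151). Chance stays open: 8 of 100 assignments of genotype within each treatment, the real one included, gave a mean as large either way (largest other -0.13), though they ignore the sets and mix differences between genotypes into the comparison, and the means within sets 2, 3 and 4 (-0.04, -0.14 and -0.12) allow 8 exchanges of the responses, too few to decide. A weaker response for want of the receptor is the biological explanation that the design names, and it may hold, but it stays untested here, the more so as the Rara probe set lay higher in the arrays labelled RARaKO.

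For single probe sets the difference between responses gave 0 calls (limma, 1168 at an unadjusted p under 0.05), and with 0 real calls all 100 assignments of genotype give as many or more by construction (highest other 3), so this count tells nothing.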

How the results depend on the processing

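No named gene or list call reversed its direction under any alternative run. The difference between responses had 0 calls under each of them. The filters on a log2 level of 4 or 6 and the intensity trend could not be run without levels, though by the recovered class the filter at 4 would have left out few probe sets. The minimum level class, the variance prior per class, the removal of the chromosome 4 segment and, for lists and overlaps, of 1 array were chosen after the data had been seen. Where no cause is named below, the cause was not tested.

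For the WT response (214 calls) array weights gave 382, the set as a fixed block 339 and a minimum of 1 log2 unit 30; leaving out sets or single arrays gave 40 to 226. For the RARaKO response (99) the fit on its own 6 arrays gave 14, the set as a fixed block 167 and as a random block 150, and the minimum of 1 log2 unit 13; leaving out gave 2 to 88. For the genotypes in vehicle (1131) array weights gave 2071, the fixed block 1972, 1 probe set per gene 736 (fewer are tested) and the minimum of 1 log2 unit 44; leaving out gave 217 to 1426, the highest without RARaKO atRA replicate 2. For the genotypes in atRA (1173) the fit on its own 6 arrays gave 592, the fixed block 2344, the random block 1925, 1 probe set per gene 751 and the minimum of 1 log2 unit 40; leaving out gave 320 to 1124. Overlaps of the responses (85) numbered 140 with the fixed block, 12 with the minimum of 1 log2 unit and 2 to 62 when leaving out. Overlaps of the genotype differences (722) numbered 1342, 25 and 169 to 602, and 452 without the segment. Pairs in the genotype comparison with atRA, one of which correlated at 0.0375, did not all pass 0.1, so its block counts are given here alone.

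Of 20 calls of lists, 5 held with an estimated correlation, 16 with the mean of all probe sets of a gene and 15 with fry. Leaving out sets or RARaKO atRA replicate 2 gave 14 to 21, some of them new. At a level class of 8 or more 7 held and 2 others were called, each higher. These were mesoderm in the RARaKO response (adjusted p = 0.0174) and known retinoic acid targets between genotypes in vehicle (0.00961). The 4 Hox calls could not be tested there. The other 9 were lost: pluripotency in the RARaKO response (0.787), the difference of known retinoic acid targets (0.0610), stress (0.0764) and FGF (0.118) in vehicle, and germline (0.0768), cell cycle (0.0578), stress (0.0768), FGF (0.220) and cholesterol synthesis (0.306) in atRA. The fixed block ended the call of cholesterol synthesis between genotypes in atRA (adjusted p = 0.120) and no other list call, and it ended 1 of the 38 named calls of the WT response (Rara) and none of the named calls of the other comparisons. Without a whole set 14 to 19 of the 38 named calls of the WT response held. Between genotypes 22 to 33 of 50 did in vehicle and 29 to 31 of 55 in atRA. The Rara difference (0.90) misses the minimum of 1 log2 unit by construction. Quantile normalization or centring of the arrays moved the share of higher calls from 61.3% to at most 64.9% in vehicle, the largest shift by scaling. Both were applied to values already centred per probe set, so the scaling of the original levels was not rechecked. Over all alternatives that share ran from 51.2% (level class of 8 or more) to 85.8% (without set 2) in vehicle and, from 51.7%, between 36.7% (level class of 8 or more) and 68.4% (without set 4) in atRA, so the balance of directions between genotypes is not settled. The number of arrays and the lost levels limit what can be told about weakly expressed genes.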

Other observations

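The tests of the chromosome 4 segment, of the single array and of other splits of the arrays were chosen only after the results had been seen. Among all chromosomes, genes of chromosome 19 with a recovered level of at least 8 also lay lower in the arrays labelled RARaKO, with a median of -0.10 in vehicle and -0.12 in atRA over 311 genes, singled out after the values were seen.

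The segment from Tusc1 to Akirin1 holds genes of several of the lists: Foxd3 and L1td1 of pluripotency, Elavl4 of the neural list, Tal1 of the mesoderm list, Jun of the immediate-early genes, and Cdc20 and Cdkn2c of the cell cycle. On the other chromosomes, no run of 25 genes of high level reached a median beyond 0.18 in size in the atRA arrays. The rest of the segment's own chromosome was not searched for runs. Among random sets of the same size, drawn from high-level genes of all chromosomes, 0 of 10000 had a median as large as the segment's. The segment had been picked for its shift in the vehicle arrays of the same lines, while the random sets were not picked. That count was therefore all but fixed beforehand.

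A correction in the authors' normalization that moved the whole level class alike is argued against as the source of the segment's shift. In the atRA arrays that class had a median of -0.03 elsewhere, and the segment lay above it by 0.590 (95% bootstrap interval 0.546 to 0.629). The run had been picked for its shift in the same lines, so the size of that excess decides nothing further. Corrections that vary within the class, or by probe sequence, were not tested. A single mislabelled array is argued against because all 12 arrays lay on the side of their label, with bounds for the atRA arrays taken from vehicle and for the vehicle arrays from atRA, which gave the same run. A candidate explanation is a difference in copy number, 3 copies in the RARaKO line for each 2 in WT, for which the log2 difference would be 0.585, and the median in the atRA arrays was 0.56 (95% bootstrap interval 0.52 to 0.60), a match that rests on the values being log2. A gain in the RARaKO line and a loss in the WT line cannot be told apart, because the values are centred and no reference is present. The same arrays carry the genotype and the segment, so other differences between genotypes could also come from the line and not from the receptor.

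The array RARaKO atRA replicate 2 had the widest spread (SD 0.201, others 0.128 to 0.163) and 143 probe sets more than 1 log2 unit above their median, where no other array had over 24. The highest, singled out after their values were seen, were Kdm5c (2.71), Pnn (2.54), the nuclear RNA Malat1 (2.38 and 2.14), Rlf (2.10) and Setd5 (2.05). This array's hybridization spike mean was -0.0275, within the range of the other arrays (-0.0362 to 0.330, the highest on WT vehicle replicate 4). Those spikes were read after GCRMA, which scales the arrays to each other, so they cannot decide on weak or strong hybridization. This array's mean 5' minus 3' difference was 0.0605, rank 9 of 12 from the lowest, and between those of RARaKO atRA replicates 3 and 4 (0.0012 and 0.0897). That rank pools groups which this measure parts. Taken singly, Actb (0.111) and Tfrc (0.208) were high on this array, while Pcx (-0.0927) was the lowest of the arrays labelled RARaKO. These probe sets were also read after GCRMA, so RNA lost from the 5' end was not seen but stays open. Cells of another type stay open: none of 6 marker lists had a median above the highest of the other arrays (largest excess -0.0129), but medians of centred values would hide a small share of such cells. The same probe sets had medians of -0.02 and 0.27 on RARaKO atRA replicates 3 and 4, of 0.44, 0.41 and 0.11 on the RARaKO vehicle arrays and between -0.37 and -0.02 on the WT arrays, and the source of the pattern stays open.

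Splits of the 6 arrays of a comparison number 10, too few for a share under 0.05. In the WT response (214 calls), the RARaKO response (99), the genotypes in vehicle (1131) and in atRA (1173), the real split was the 1 split of 10 with as many calls, and the highest of the others gave 0. Also 0 was the highest among the other 3 splits that part all 3 same-numbered pairs. Each other split mixes arrays of the real groups, so a real difference adds to the spread within its groups and lowers its calls. These counts of 0 are therefore no separate support.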
